A study of Mus musculus with 12 samples.

How the data were processed

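RNA from sorted LSK cells of a mouse bone marrow transplant experiment was selected for polyA and sequenced in 12 libraries, 3 each of vehicle, palbociclib, ruxolitinib and the combination. Per the labels, bone marrow was depleted of lineage-positive cells on magnetic columns and the Lin-negative, Sca-1-positive, Kit-positive cells were then sorted by flow cytometry. The submitters' processing notes name fastp 0.20.0, HISAT2 2.0.1, SAMtools 1.10, featureCounts 2.0.0, DESeq2 without a version and the genome build GRCm38, without settings.

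The values used here were the 3 deposited tables of the authors' DESeq2 fit, each comparing a drug arm with vehicle, with 55487 genes. The base mean is a signal that the authors computed as the mean of size-factor normalised counts over all libraries of their fit, the same in all 3 tables. The log2 fold change and its standard error are the authors' estimates of the log2 ratio of treated to vehicle from the DESeq2 model, without shrinkage. The score is the Wald statistic that the authors computed, the log2 fold change over its standard error. The deposited p-value is the authors' 2-sided p of that statistic, and the adjusted p is their Benjamini-Hochberg value after independent filtering. Values per sample were not used here, so nothing was refitted and the folds, errors and adjusted p against vehicle are the authors' own. A gene passed at an adjusted p under 0.05. "Rose" and "fell" are used for genes that passed.

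Group levels and size factors were solved from the tables with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. The base means and the errors showed that the authors' fit held 24 libraries, the 12 of these groups and 12 others. For each gene the 3 standard errors give 3 equations in 2 unknowns, the vehicle level and the dispersion, and they were met within 1e-06 for 19080 of the 19228 genes tested in the combination (99.2%). The implied reads in genes ranged from 18.2 to 44.8 M reads a library. The 95% intervals of levels use the deposited errors, and a floor of 3 reads over a group bounds folds against a group at 0; these cover counting error and the modelled spread only. Coordinates and gene types came from GENCODE mouse release 21 on GRCm38, which holds 55227 of the gene identifiers (99.5%).

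Differences between the combination and each single drug, and the departure of the combination from the sum of both drugs, were tested by the difference of deposited fold changes over the root of the summed squared errors (2-sided normal, Benjamini-Hochberg). This ignores the positive covariance from the shared vehicle libraries. Alternatives with a correlation of 0.5 between estimates and, added after the data were seen, with group variances recovered from the deposited errors were run beside it.

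Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison. The lists covered the cell cycle, signalling, stress, metabolism, translation, blood lineages, the sort gate, the drug targets and sex-linked genes. They, the tests, the thresholds and the alternatives in the closing section were chosen before the data were examined, apart from those said to be added. Medians were also ranked among 10000 random lists of the same size drawn within 20 bins of expression. Lists of plasma cell genes, X-linked partners of Y genes and imprinted genes were added for the closing section. Their adjusted p covers only these 3 lists, and no value at a correlation of 0.05 was taken.

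The rule for named genes, also fixed beforehand, took per comparison with vehicle the 10 largest rises and falls among genes that passed with a base mean of at least 50 and an ordinary symbol. It took 5 each way for differences, up to 3 members of each list with the smallest p, and all sort genes and drug targets. Immunoglobulin and Y-linked genes filled much of the first part, so the same rule without them was added after the values were seen. List members and other genes named beyond these rules were chosen after their values were seen.

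The methods were tested on simulated data with the recovered dispersions, with 200 changed genes, of which 100 changed 2-fold and 100 changed 4-fold. Among all 19080 genes, the combination test found 79% and 95% of them in their direction. It also called 686 unchanged genes, 79.8% of all calls, and 94.3% of those had a base mean under 10. The test was then restricted to a base mean of at least 50 after that result: 76% and 95% were found and 7 of 11708 genes were called without a change (3.93% of calls). Among all genes the conservative differences of the combination from ruxolitinib, from palbociclib and from the sum called 395, 408 and 449 unchanged genes, 72.1%, 73.0% and 77.7% of their calls, nearly all at a base mean under 10. So counts over all 19228 genes can hold false calls at low counts, and the word conservative refers to the covariance alone. At a base mean of at least 50 the conservative difference between the combination and ruxolitinib found 54% and 91%, with palbociclib 55% and 89%, and the additivity test 36% and 85%, each with 0 unchanged genes called. With recovered variances these were 79% and 94%, 78% and 96%, and 57% and 89%, with 5, 4 and 9 unchanged genes called. A planted list of 20 genes had an adjusted p of 3.9e-32, and 0 of 20 random lists passed. Plots were drawn with matplotlib 3.10.9.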

Results

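RNA was sequenced from LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of mouse bone marrow that holds stem cells and multipotent progenitors. The cells came from a bone marrow transplant experiment on the C57BL/6 background, with a genotype labelled homozygous for JAK2V617F, the activating kinase mutation of human myeloproliferative neoplasms. The 12 libraries formed 4 groups of 3: vehicle, palbociclib (an inhibitor of CDK4 and CDK6), ruxolitinib (an inhibitor of JAK1 and JAK2) and the combination of both drugs. The reads in genes implied by the deposited tables were 31.5, 31.7 and 34.8 M reads for the vehicle libraries and 25.1, 25.1 and 30.1 M for the palbociclib libraries. The ruxolitinib libraries held 21.5, 32.6 and 34.1 M reads, and the combination libraries 18.2, 22.6 and 44.8 M. The labels do not say that the libraries of a group came from separate animals, so the p-values may not measure a spread between animals. The authors' fit also held 12 other libraries, which enter its modelled spread.

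The comparison of palbociclib with vehicle asked what blocking the cyclin D kinases changes in these progenitors. The lists of mitotic and monocyte genes shifted down, and those of stem cell genes and cholesterol synthesis shifted up, with 21 of 65, 9 of 21, 15 of 23 and 7 of 24 members passing. In the granulocyte list members went both ways: Ltf and Mmp9 were among those that rose, and Elane among those that fell. In the authors' deposited table, 770 genes were higher and 563 lower among 15448 tested. Among protein-coding genes without immunoglobulin, T cell receptor and Y-linked genes, a count added after the data were seen, 665 were higher and 538 lower.

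Of the 65 genes of the G2/M and mitosis list, 21 fell with palbociclib and 44 did not pass the test, with a median log2 fold change of -0.86. Adjusted over the list alone, 52 fell. The list shifted down in limma's cameraPR (adjusted p = 9.3e-23), and the fold changes of all 65 members were below 0. The authors' deposited table gave log2 fold changes of -1.30 ± 0.33 (standard error) for the proliferation marker Mki67 (adjusted p = 0.0034), -1.17 ± 0.31 for the mitotic kinase Plk1 (adjusted p = 0.0057) and -0.86 ± 0.23 for the condensin gene Smc2 (adjusted p = 0.0067). The modelled level of Mki67 was 25286 normalised reads in vehicle and 10262 with palbociclib. The list of S phase genes and E2F targets had a median of -0.16, and 56 of its 56 members did not pass the DESeq2 test, 5 of them with an unadjusted p under 0.05. Its adjusted p was 0.022 and became 0.18 at an inter-gene correlation of 0.05. In the list of the CDK-RB machinery, 4 of 24 genes rose and 2 fell, and the list as a whole did not shift (adjusted p = 0.88), with a median of -0.12 and a mean statistic just above 0. The authors' deposited table showed Ccnd1, which encodes cyclin D1, at 1.66 ± 0.25 (adjusted p = 7.8e-08), Ccnd2 at 0.76 ± 0.17 (adjusted p = 0.00075) and the CDK inhibitor gene Cdkn1c at 1.46 ± 0.35 (adjusted p = 0.0016).

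Of 23 stem cell genes, 15 rose with palbociclib and 8 did not pass the test, and 18 rose when adjusted over the list alone (median 1.25, adjusted p = 1.1e-13). The authors' deposited table gave 1.39 ± 0.32 for Procr (adjusted p = 0.0011) and 1.31 ± 0.28 for Tie1 (adjusted p = 0.00024). In the megakaryocyte list 2 of 22 genes rose, 9 when adjusted over the list alone, with a median of 0.61 (adjusted p = 0.00028). The authors' deposited table gave 1.94 ± 0.55 for Trpc6 (adjusted p = 0.01) and 1.97 ± 0.64 for Mmrn1 (adjusted p = 0.031). In the list of lymphoid-primed progenitor genes, Cd27 rose while Satb1 and Notch1 fell (median -0.57, adjusted p = 0.044, and 0.12 at a correlation of 0.05).

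Among 21 genes of monocytes, macrophages and dendritic cells, 9 fell with palbociclib and 12 did not pass the test, and 10 fell when adjusted over the list alone (median -0.82, adjusted p = 1.7e-09). The authors' deposited table gave -2.23 ± 0.34 for Csf1r, the receptor of macrophage colony-stimulating factor (adjusted p = 9.1e-08), -2.0 ± 0.30 for the transcription factor gene Irf8 (adjusted p = 5.7e-08) and -2.90 ± 0.51 for Ly86 (adjusted p = 5.2e-06). In the granulocyte list 10 of 22 genes rose and 4 fell, 12 and 7 when adjusted over the list alone (median 1.43, adjusted p = 0.011, and 0.078 at a correlation of 0.05). Those that rose included Ltf and Mmp9, at 7.94 ± 1.47 and 8.0 ± 1.53 in the authors' deposited table (adjusted p = 1.5e-05 and 3.5e-05), with Ngp at 7.17 ± 1.57, Camp at 6.90 ± 1.77 and S100a9 at 4.92 ± 1.5. Those that fell included Elane, which encodes neutrophil elastase, at -3.35 ± 0.65 in the authors' deposited table (adjusted p = 4.8e-05). The modelled level of Ltf was 6.35 normalised reads in vehicle, 1563 with palbociclib and 6.42 with ruxolitinib. Whether 1 or all 3 palbociclib libraries carried these rises cannot be read from group levels. Granulocytes or their RNA left in the sorted libraries were not tested as a source. Of 29 erythroid genes 3 fell, 11 when adjusted over the list alone (median -0.83, adjusted p = 0.0045, and 0.067 at a correlation of 0.05), among them Tspo2, Ermap and Gata1. The authors' deposited table put these at -2.50 ± 0.64, -2.31 ± 0.75 and -0.78 ± 0.25. The mast cell genes Hdc and Ms4a2 also fell, at -2.09 ± 0.39 and -1.51 ± 0.41 in the authors' deposited table, while their list of 15 genes did not shift (adjusted p = 0.065).

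Of 24 genes of cholesterol synthesis, 7 rose with palbociclib and 17 did not pass the test, and 12 rose when adjusted over the list alone (median 0.53, adjusted p = 7.1e-07). With log2 fold changes in place of the test statistic the list did not pass (adjusted p = 0.20). The authors' deposited table gave 1.01 ± 0.29 for Mvd, an enzyme of the pathway (adjusted p = 0.012). Feedback targets of the ERK pathway shifted up, with 4 of 13 genes passing and 6 when adjusted over the list alone (median 0.42, adjusted p = 0.0011). They included Dusp4, Spry4 and Etv4, at 1.78 ± 0.44, 1.96 ± 0.55 and 2.36 ± 0.64 in the authors' deposited table. In the interferon response list 5 of 42 genes rose, 6 when adjusted over the list alone (median 0.31, adjusted p = 0.0018, and 0.067 at a correlation of 0.05). The authors' deposited table gave 1.31 ± 0.28 for Isg15, 1.01 ± 0.25 for Rtp4 and 0.60 ± 0.15 for Ifitm3. Targets of TNF and NF-kB shifted down (median -0.28, adjusted p = 0.021, and 0.12 at a correlation of 0.05), with 1 of 28 passing, Birc3. The profibrotic mediators shifted up (median 0.52, adjusted p = 0.034, and 0.12 at a correlation of 0.05), with S100a9, Mmp9 and Cxcl12 passing out of 16. S100a9 and Mmp9 are also members of the granulocyte list, so this shift is not separate from the rises there.

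Among the genes that define the sort, Ly6a, which encodes Sca-1, rose with palbociclib, at 1.07 ± 0.35 in the authors' deposited table (adjusted p = 0.032). Kit was at 0.12 ± 0.18 in the authors' deposited table and did not pass (adjusted p = 0.77). Of 9 genes of the drug target kinases and their STAT partners, Jak3 rose, at 0.47 ± 0.15 in the authors' deposited table (adjusted p = 0.032). Cdk4 and Cdk6 were at 0.14 ± 0.16 and -0.51 ± 0.20 in the authors' deposited table (adjusted p = 0.69 and 0.079). Outside the immunoglobulin and Y-linked genes, among genes at a base mean of at least 50 and with an ordinary symbol, the largest falls beside Elane were those of Sgms2, Rab7b, Il2, Ly86, Mefv, Tifab, Clec5a, Sfrp4 and Cldn15, from -3.0 for Sgms2 to -2.79 for Cldn15 in the authors' deposited table. Eno1b, Slc17a8 and Eya4 were among the largest rises, at 5.98 ± 0.64, 3.94 ± 0.93 and 4.01 ± 1.26 in the authors' deposited table.

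Immunoglobulin segments and Y-linked genes moved with these groups. Of 186 immunoglobulin segments 43 were higher with palbociclib and 3 lower in the authors' deposited table, and immunoglobulin genes with Jchain took 0.481% of all normalised reads against 0.0827% in vehicle. Ighv3-8, with a modelled 4.69 normalised reads in vehicle and 3007 with palbociclib, was at 9.33 ± 1.5 in the authors' deposited table. Of the 7 Y-linked genes tested 4 were lower and 1, Gm47283, was higher, as it was in the other 2 comparisons, and the sex-linked list shifted down (adjusted p = 7.1e-07). Ddx3y was at -6.71 ± 1.40, Kdm5d at -8.30 ± 1.46, Uty at -6.53 ± 1.19 and Eif2s3y at -5.96 ± 1.30 in the authors' deposited table. The modelled level of Ddx3y was 422 normalised reads in vehicle (95% interval 117 to 1520) and 4.03 with palbociclib (0.989 to 16.4). The labels give no sex for donors or recipients. If cells of the palbociclib and combination groups differed in origin from those of vehicle, every palbociclib result here would carry that difference too.

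The comparison of ruxolitinib with vehicle asked what inhibiting the mutant kinase changes in the same cells. The lists of 4 mature lineages shifted down, with 8 of 29 erythroid, 7 of 22 granulocyte, 8 of 21 monocyte and 4 of 15 mast cell genes passing. The stem cell list shifted up with 4 of 23 genes passing, and the list of mitotic genes did not shift. In the authors' deposited table, 144 genes were higher and 314 lower among 15448 tested. Without immunoglobulin, T cell receptor and Y-linked genes, 134 protein-coding genes were higher and 293 lower.

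Of 29 erythroid genes, 8 fell with ruxolitinib and 21 did not pass the test, and 18 fell when adjusted over the list alone (median -1.27, adjusted p = 6.4e-12). The authors' deposited table gave -1.03 ± 0.25 for the erythroid transcription factor gene Gata1 (adjusted p = 0.0042), -2.97 ± 0.75 for Ermap (adjusted p = 0.0073) and -2.78 ± 0.64 for Tspo2 (adjusted p = 0.003). Of 22 granulocyte genes 7 fell, 10 when adjusted over the list alone (median -1.21, adjusted p = 4.3e-08). The chemokine receptor gene Cxcr2 was at -1.91 ± 0.39, Prtn3 at -1.18 ± 0.26 and Gstm1 at -1.15 ± 0.23 in the authors' deposited table (adjusted p = 0.00041, 0.0013 and 0.00022). Of 21 monocyte, macrophage and dendritic cell genes 8 fell, 9 when adjusted over the list alone (median -0.94, adjusted p = 5.3e-07). The authors' deposited table gave -2.41 ± 0.52 for F13a1, -1.92 ± 0.34 for Csf1r and -1.82 ± 0.38 for Cx3cr1 (adjusted p = 0.00088, 2.1e-05 and 0.00056). Of 15 mast cell, basophil and eosinophil genes 4 fell, 10 when adjusted over the list alone (median -1.73, adjusted p = 2.3e-07). Hdc, Ms4a2 and Fcer1a, the last 2 of them encoding chains of the IgE receptor, were at -1.90 ± 0.39, -1.73 ± 0.41 and -1.72 ± 0.42 in the authors' deposited table.

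In the stem cell list 4 of 23 genes rose with ruxolitinib and 19 did not pass the test, and 6 rose when adjusted over the list alone (median 0.75, adjusted p = 2.3e-07). They were Cdkn1c, Tie1, Procr and Fgd5, at 1.24 ± 0.35, 1.01 ± 0.28, 1.06 ± 0.32 and 1.48 ± 0.46 in the authors' deposited table. The feedback targets of ERK shifted up with 1 gene passing, Dusp4 (list median 0.16, adjusted p = 0.04, and 0.13 at a correlation of 0.05). Targets of TNF and NF-kB shifted down (median -0.23, adjusted p = 0.0024, and 0.054 at a correlation of 0.05), with Tnfaip2 at -0.99 ± 0.23 and Birc3 at -0.69 ± 0.16 in the authors' deposited table. The fixed list of JAK-STAT targets did not pass in cameraPR (median -0.27, adjusted p = 0.18). Its median lay at percentile 0 among random lists of like expression, and 17 of 21 fold changes were below 0. By DESeq2 21 of its 21 members did not pass, 2 of them with an unadjusted p under 0.05. The G2/M list was at a median of -0.10 (adjusted p = 0.29) and the S phase list at 0.11 (adjusted p = 0.11).

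Among genes at a base mean of at least 50 and with an ordinary symbol, the largest rises with ruxolitinib outside the immunoglobulin genes were those of the growth factor gene Ptn and the kinase gene Mapk12, at 3.14 ± 0.54 and 3.09 ± 0.49 in the authors' deposited table (adjusted p = 6.8e-06 and 6.4e-07). Erdr1, Il17rc, Tcf15, Npdc1, Ankrd63, Cavin3, Insrr and Mpdz followed, each at or below the 2.51 of Erdr1 in the authors' deposited table. Among the same genes the largest falls outside the immunoglobulin genes were those of Abcg4, F10, Ccl6, Tlcd4, Lilr4b, Pkhd1l1 and Paqr9, from -3.54 for Abcg4 to -3.05 for Paqr9 in the authors' deposited table. Of 186 immunoglobulin segments 16 were lower and 1 higher in the authors' deposited table, led by Igkv5-39 at -8.20 ± 1.33 and Ighg1 at -8.10 ± 2.35. Immunoglobulin genes with Jchain took 0.0227% of the normalised reads. Ly6e, a member of the Sca-1 gene family in the list of sort genes, fell, at -0.42 ± 0.12 in the authors' deposited table (adjusted p = 0.031), and Ly6a was at 0.21 ± 0.35 (adjusted p = 0.89). Jak2 was at -0.30 ± 0.19 in the authors' deposited table (adjusted p = 0.56). The Y-linked genes that fell with palbociclib did not pass here, with Ddx3y at 1.40 ± 1.33 in the authors' deposited table.

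**Figure D1:**
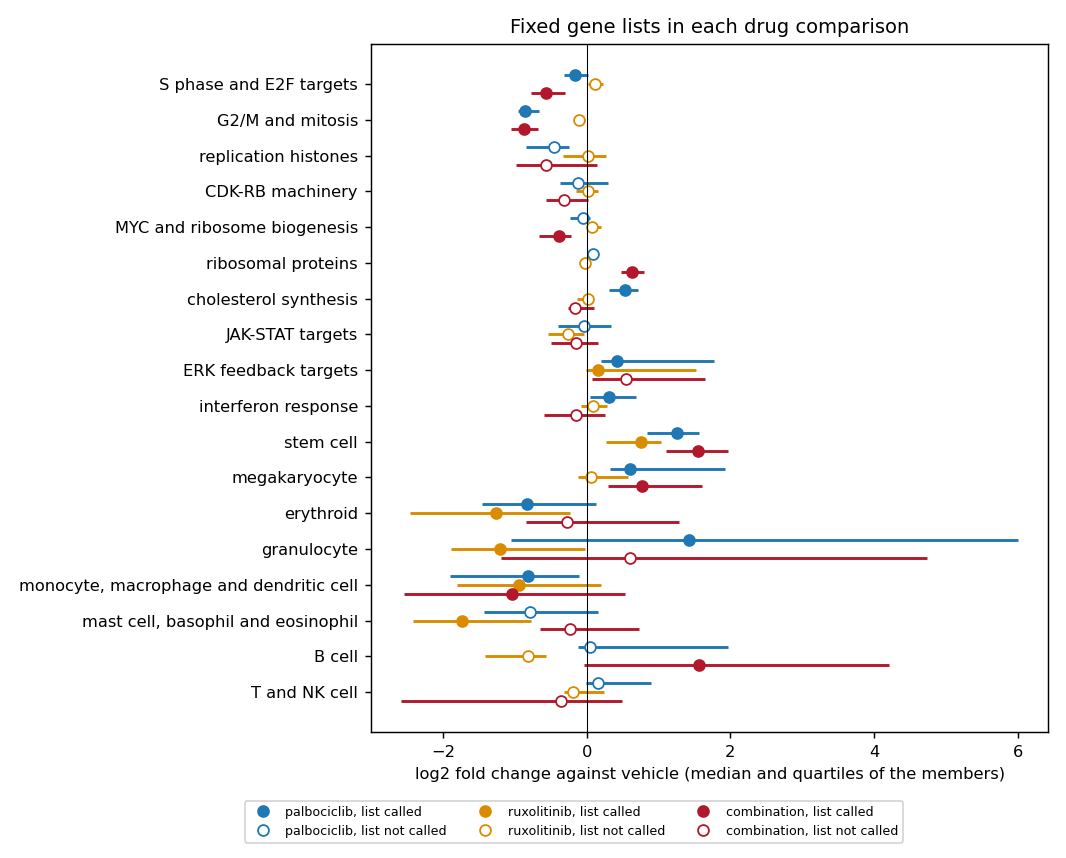
Median log2 fold change against vehicle (dots) with the quartiles of the members (lines) for 18 fixed gene lists, in the palbociclib, ruxolitinib and combination comparisons, where filled dots mark lists with an adjusted p under 0.05 in limma's cameraPR. The stem cell medians lie above 0 for each drug arm, at 1.25, 0.75 and 1.55, and the ribosomal protein median is at 0.63 in the combination.

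The comparison of the combination with vehicle asked what both drugs did together. Of 23 stem cell genes 21 rose, and of 75 ribosomal protein genes 59 rose. The lists of S phase, mitotic, ribosome biogenesis and monocyte genes shifted down, with 22 of 56, 38 of 65, 16 of 32 and 11 of 22 members lower. Erythroid genes as a list did not shift. Immunoglobulin and plasma cell transcripts were far above vehicle. In the authors' deposited table, 2471 genes were higher and 1960 lower among 19228 tested. Without immunoglobulin, T cell receptor and Y-linked genes, 1806 protein-coding genes were higher and 1891 lower.

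Of 23 stem cell genes 21 rose in the combination, 22 when adjusted over the list alone (median 1.55, adjusted p = 1.9e-14). The authors' deposited table gave 2.27 ± 0.32 for Procr (adjusted p = 1e-09), 1.92 ± 0.33 for Esam (adjusted p = 6.4e-07) and 4.99 ± 0.85 for Sult1a1 (adjusted p = 6.7e-07). The modelled level of Hlf, a transcription factor of stem cells, was 4105 normalised reads in vehicle, 6007 with palbociclib, 6571 with ruxolitinib and 8262 in the combination. Of 23 megakaryocyte genes 8 rose, 10 when adjusted over the list alone (median 0.77, adjusted p = 0.0021), among them Trpc6, Ppbp and Clec1b at 2.58 ± 0.55, 3.21 ± 0.73 and 4.04 ± 1.12 in the authors' deposited table. With log2 fold changes in place of the test statistic the megakaryocyte list did not pass (adjusted p = 0.19). Ly6a rose, at 1.83 ± 0.35 in the authors' deposited table (adjusted p = 1.1e-05), from a modelled 1004 to 3557 normalised reads. Kit rose as well, at 0.48 ± 0.18 in the authors' deposited table (adjusted p = 0.035). Ly6a carries the identifier ENSMUSG00000075602 and lies on chromosome 15 from 74994877 to 74998031 in GRCm38.

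Of 65 G2/M genes 38 fell in the combination and 27 did not pass the test, and 50 fell when adjusted over the list alone (median -0.88, adjusted p = 8.2e-16). Smc2, Kif15 and Smc4 were at -1.13 ± 0.23, -1.16 ± 0.29 and -0.82 ± 0.20 in the authors' deposited table (adjusted p = 5.9e-05, 0.0013 and 0.0011). Of 56 S phase genes and E2F targets 22 fell, 27 when adjusted over the list alone (median -0.57, adjusted p = 2.7e-10). The authors' deposited table gave -1.01 ± 0.26 for the polymerase gene Pola1, -0.90 ± 0.22 for Dnmt1 and -0.82 ± 0.22 for the ribonucleotide reductase gene Rrm1 (adjusted p = 0.0016, 0.00086 and 0.0019). In the CDK-RB list 3 of 25 genes rose and 5 fell (adjusted p = 0.067 for the list). Cdk6, on chromosome 5 from 3341485 to 3531008, fell, at -0.73 ± 0.20 in the authors' deposited table (adjusted p = 0.0025). E2f8 and E2f4 were at -1.15 ± 0.25 and -0.63 ± 0.13, and Ccnd1 at 1.17 ± 0.25, in the authors' deposited table (adjusted p = 0.00017, 4.6e-05 and 0.00015).

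Of 32 genes of MYC and ribosome biogenesis 16 fell, 18 when adjusted over the list alone (median -0.38, adjusted p = 1.1e-07). Cad, an enzyme of pyrimidine synthesis, and the nucleolar genes Nolc1 and Utp20 were at -1.09 ± 0.25, -0.92 ± 0.22 and -0.82 ± 0.20 in the authors' deposited table. Of 75 ribosomal protein genes 59 rose, 62 when adjusted over the list alone (median 0.63, adjusted p = 7e-17), with Rpl23 at 0.63 ± 0.14 and Rplp2 at 1.11 ± 0.26 in the authors' deposited table. Their share of the normalised reads was 10.6%, against 7.33% in vehicle, 8.10% with palbociclib and 7.33% with ruxolitinib. After a fit of all fold changes on transcript length and GC content their median was 0.24. Non-coding genes and pseudogenes moved in the same group: 525 of 4715 were higher and 58 lower in the authors' deposited table. Of all 14249 protein-coding genes 1807 were higher and 1895 lower, so the share higher was no larger among non-coding genes. The classes differed in how few non-coding genes were lower. Calls at low counts can be false, and non-coding genes were not counted separately at a base mean of at least 50. The level of CT010467.1, annotated with no gene name, was 4.74 times that of vehicle. With log2 fold changes in place of the test statistic the ribosomal protein list did not pass (adjusted p = 0.48), nor did MYC and ribosome biogenesis (adjusted p = 0.073). Of 12 heat shock genes 4 fell (median -0.24, adjusted p = 0.0053, and 0.064 at a base mean of at least 50), with Hsph1 at -0.91 ± 0.24 and Hspd1 at -0.72 ± 0.17 in the authors' deposited table. Of 18 genes of hypoxia and glycolysis Eno1, Ero1l and Pfkp fell (list median -0.19, adjusted p = 0.049, and 0.15 at a correlation of 0.05). Among random lists of like expression the heat shock median lay at percentile 21.02 and the hypoxia and glycolysis median at 25.49. Neither median therefore stood out from genes of like expression.

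Of 22 genes of monocytes, macrophages and dendritic cells 11 fell and 1 rose in the combination, as they did when adjusted over the list alone (median -1.04, adjusted p = 3.4e-06). The authors' deposited table gave -3.50 ± 0.40 for the chemokine receptor gene Cx3cr1 (adjusted p = 4e-15), -2.57 ± 0.35 for Csf1r (adjusted p = 8.7e-11) and -2.34 ± 0.31 for Irf8 (adjusted p = 2.1e-11). In the granulocyte list 7 of 23 genes rose and 7 fell. Its median of 0.60 and its test, which pointed down, differed in sign, and the list did not pass (adjusted p = 0.79). Elane, Mpo and Prtn3 fell, at -3.79 ± 0.65, -2.80 ± 0.45 and -1.44 ± 0.26 in the authors' deposited table, and Mmp9, Retnlg and Lyz2 rose, at 5.96 ± 1.53, 5.75 ± 1.55 and 1.05 ± 0.18. In the erythroid list 6 of 29 genes rose and 2 fell (median -0.27, adjusted p = 0.96, with a mean statistic above 0). Those that rose were the globin genes Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 with Alas2 and Slc4a1, and those that fell were Gata1 and Tspo2. Hbb-bt was at 3.41 ± 0.72 and Gata1 at -0.88 ± 0.25 in the authors' deposited table. The mast cell gene Hdc fell, at -2.47 ± 0.39 in the authors' deposited table, and its list did not shift (adjusted p = 0.73).

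Pathways that shifted with palbociclib alone did not all do so in the combination. The cholesterol list was at a median of -0.17 (adjusted p = 0.31), with 1 of 24 genes lower, Hmgcs1 at -0.62 ± 0.21 in the authors' deposited table. In the interferon list 3 of 42 genes rose and 6 fell (median -0.15, adjusted p = 0.22). Ifitm3 was at 0.62 ± 0.15, Rtp4 at -0.79 ± 0.26 and Gbp3 at -0.84 ± 0.19 in the authors' deposited table. Of 13 feedback targets of ERK 4 rose (median 0.55, adjusted p = 0.064), among them Spry4 at 2.57 ± 0.55 and Dusp4 at 1.91 ± 0.44 in the authors' deposited table. The JAK-STAT target list did not shift with palbociclib (adjusted p = 0.93) or in the combination (adjusted p = 0.78).

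In the authors' deposited table, 135 of 203 immunoglobulin segments were higher in the combination and 2 lower. Immunoglobulin genes with Jchain took 7.59% of the normalised reads, 97.0 times their level in vehicle, and Igha alone took 3.79%. Igha, Igkc and Jchain were at 7.52 ± 1.06, 6.94 ± 0.93 and 7.64 ± 0.98 in the authors' deposited table. Segments with no read in vehicle give a lower bound only, set by 3 reads over the group: Ighv1-50 was at least 545-fold higher and Igkv3-10 at least 450-fold higher. Of 12 B cell genes 5 rose, 6 when adjusted over the list alone, with 1 lower (median 1.57, adjusted p = 0.011). They hold Igkc itself, with Cd79a at 5.69 ± 1.14 and Cd79b at 1.28 ± 0.29 in the authors' deposited table. Outside the immunoglobulin segments, among genes at a base mean of at least 50 and with an ordinary symbol, Jchain, Tnfrsf17, Ccr10, Mmp9, Eno1b, Ly6d, Mzb1, Cd79a, Pou2af1 and Cacna1h showed the largest rises, from 7.64 for Jchain to 5.49 for Cacna1h in the authors' deposited table. Among the same genes the largest falls beside the Y-linked genes were those of Mefv, C2cd4a, Cldn15, Igsf6, Elane, Hspa1b, Cx3cr1, C3, Fcgr4 and Sgms2, from -4.59 for Mefv to -3.24 for Sgms2 in the authors' deposited table. Below that base mean, Hspa1a and Ncr1 were at 0 reads in the combination by levels recovered from the authors' deposited table, so their folds are lower bounds, at least 61.6-fold and at least 7.36-fold below vehicle. Ddx3y, Kdm5d, Uty and Eif2s3y were lower than in vehicle here too, and the sex-linked list shifted down (adjusted p = 4.4e-05). Ddx3y, on chromosome Y from 1260771 to 1286629, had a modelled level of 0.925 normalised reads (95% interval 0.152 to 5.63).

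**Figure D2:**
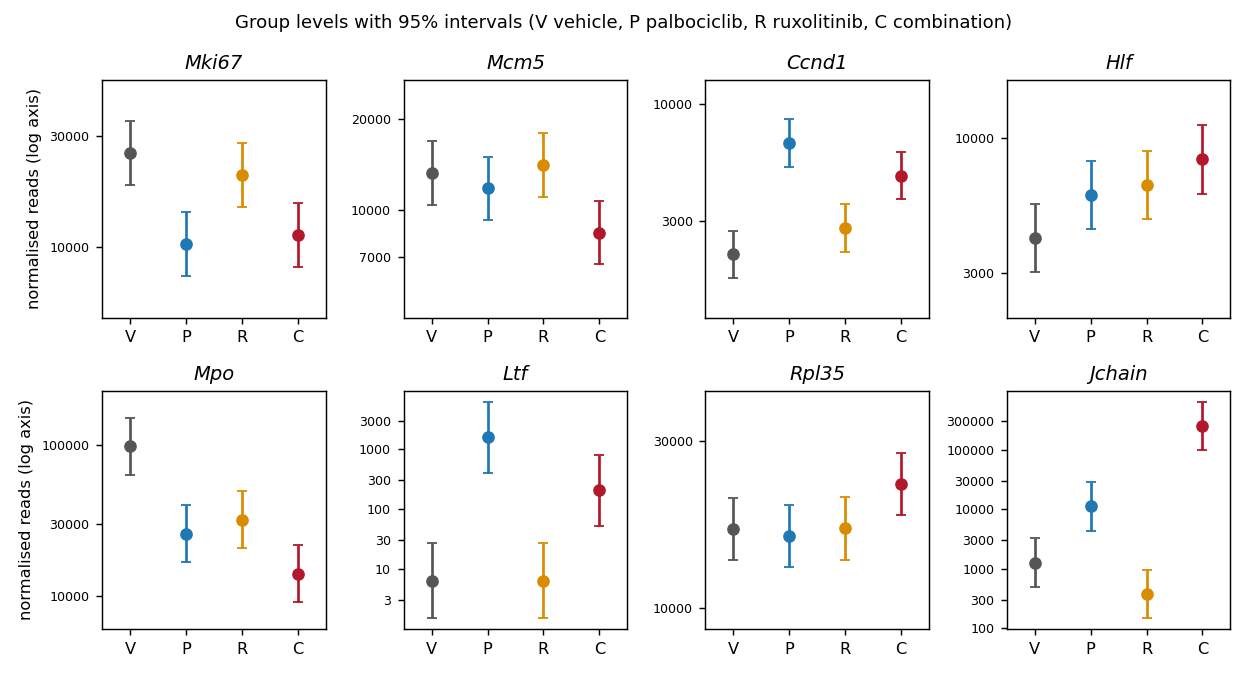
Modelled level of 8 genes in each of the 4 groups, in normalised reads on a log axis, with 95% intervals from the deposited standard errors (3 libraries a group). Mki67 fell in both palbociclib arms, at 10262 and 11228 against 25286 in vehicle, and Ltf stood at 1563 with palbociclib and 6.42 with ruxolitinib.

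What palbociclib added to ruxolitinib was read from the difference of the deposited fold changes. The lists of stem cell and ribosomal protein genes were shifted up in the combination relative to ruxolitinib, and those of S phase, mitotic and ribosome biogenesis genes down, while few of their single genes passed. The test, which ignores the covariance from the shared vehicle libraries and is called conservative below for that reason, found 178 genes higher and 34 lower among 19228. With variances recovered from the deposited errors, an alternative added after the data were seen, 1805 were higher and 1215 lower. In cameraPR 15 of 33 lists shifted. The S phase list was at a median of -0.68 (adjusted p = 1.7e-17), the G2/M list at -0.73 (adjusted p = 1.2e-15) and MYC and ribosome biogenesis at -0.57 (adjusted p = 4.9e-13). Ribosomal proteins were at 0.66 (adjusted p = 8.2e-23), stem cell genes at 0.87 (adjusted p = 4.9e-06) and erythroid genes at 1.26 (adjusted p = 1.8e-06). The granulocyte list, at 2.85, was also higher (adjusted p = 0.0012). By the conservative test 0 of 56 S phase genes, 0 of 65 G2/M genes, 0 of 32 of ribosome biogenesis, 2 of 75 ribosomal protein genes and 0 of 23 stem cell genes passed. At an unadjusted p under 0.05 these were 26, 21, 17, 56 and 8. With the recovered variances added later, 28 of 56 S phase genes, 23 of 65 G2/M genes and 18 of 32 of ribosome biogenesis were lower, and 59 of 75 ribosomal protein genes and 8 of 23 stem cell genes higher.

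Among the genes that passed the conservative test, Ddit4, a stress-induced inhibitor of mTOR signalling, differed by 2.08 ± 0.39 (adjusted p = 0.00011), Lyz2 by 1.11 ± 0.25 (adjusted p = 0.0039) and Nfkbia by 1.16 ± 0.31 (adjusted p = 0.021). Rtp4, an interferon-induced gene, differed by -1.37 ± 0.36 (adjusted p = 0.019), Recql4 by -1.30 ± 0.34 (adjusted p = 0.021), Pop1 by -1.02 ± 0.27 (adjusted p = 0.026) and Disc1 by -2.13 ± 0.59 (adjusted p = 0.033). Of the higher calls 81 were immunoglobulin segments, and plasma cell genes such as Mzb1 and Tnfrsf17 were higher, at 8.95 ± 2.10 and 7.95 ± 1.95. Ly6a differed by 1.61 ± 0.49 and did not pass (adjusted p = 0.07), but did with recovered variances (adjusted p = 0.00025).

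What ruxolitinib added to palbociclib showed in lists more than in single genes. The lists of cholesterol synthesis, S phase, interferon and granulocyte genes were shifted down in the combination relative to palbociclib alone, and those of ribosomal protein and B cell genes up. The conservative test found 3 genes: Ighe was higher, and Rtp4 and Cgn were lower. Ighe and Cgn had base means of only 8.22 and 5.41 in the authors' deposited table, and each rests on a group at 0 reads, so that its fitted difference has no bound. Rtp4, on chromosome 16 from 23520291 to 23614222, differed by -1.80 ± 0.36 (adjusted p = 0.0041). Its modelled level was 316 normalised reads in vehicle, 633 with palbociclib, 470 with ruxolitinib and 182 in the combination. At an unadjusted p under 0.05 there were 987 genes, and with recovered variances 272 passed, 188 higher and 84 lower.

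The cholesterol list was at a median of -0.66 in this difference (adjusted p = 3.9e-14), with 7 of 24 genes lower by recovered variances. Mvd differed by -1.31 ± 0.41. It did not pass the conservative test (adjusted p = 0.75), but did with recovered variances (adjusted p = 0.0041). The interferon list was at -0.37 (adjusted p = 1.8e-09), with 7 of 42 genes lower by recovered variances, among them Isg15, which differed by -1.43 ± 0.41 (adjusted p = 0.00076 with recovered variances). By the conservative test 1 of 42 interferon genes, Rtp4, and 0 of 24 cholesterol genes passed, with 10 and 13 at an unadjusted p under 0.05. The S phase list was at -0.39 (adjusted p = 5.3e-10), MYC and ribosome biogenesis at -0.31 (adjusted p = 2.7e-09) and heat shock at -0.34 (adjusted p = 0.0013). The granulocyte list was at -1.63 (adjusted p = 0.00019). Of 56 S phase and 23 granulocyte genes 0 passed by the conservative test or by recovered variances, with 0 and 1 at an unadjusted p under 0.05. Ribosomal proteins were at 0.54 (adjusted p = 1.1e-28), B cell genes at 1.11 (adjusted p = 0.00019) and erythroid genes at 0.56 (adjusted p = 0.001). Of 75 ribosomal protein genes 0 passed the conservative test, 37 had an unadjusted p under 0.05 and 3 passed with recovered variances, and of 12 B cell genes the numbers were 0, 4 and 3. The stem cell list was at 0.25 (adjusted p = 0.015, and 0.092 at a correlation of 0.05). The G2/M list did not shift.

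If the drugs acted independently on the log scale, the combination would sit at the sum of their fold changes. The ribosomal protein, erythroid, mast cell and B cell lists were shifted above that sum, and the lists of S phase, ribosome biogenesis, interferon and cholesterol genes below it. All 3 fold changes share the vehicle libraries. A deviation of vehicle alone would move a list off the sum, against its direction with the single drugs. The B cell list also holds Igkc, which belongs to the immunoglobulin rise. The conservative test found 12 genes off the sum, 8 above and 4 below. Rtp4 was at -2.38 ± 0.43 (adjusted p = 0.00029), Rai14 at -1.30 ± 0.28 (adjusted p = 0.015) and Camsap2 at 3.14 ± 0.75 (adjusted p = 0.047). The immunoglobulin genes Igkc and Ighe with 5 variable segments made up the other 7 above, and Cgn and Gm49493 were the other 2 below. Of the 11 with modelled levels, Ighe, Igkv6-20, Ighv2-3, Ighv5-12 and Cgn had a group at 0 reads, so their departures rest on folds without a bound, and 6 had none. With recovered variances 266 genes passed, 187 above and 79 below. Ribosomal proteins were at 0.58 (adjusted p = 3.3e-17), B cell genes at 1.68 (adjusted p = 3.6e-05), the erythroid list at 1.82 (adjusted p = 2.2e-13) and the mast cell list at 1.84 (adjusted p = 2.2e-06). The fit on length and GC content was not made for this sum or for both differences, so that bias of ribosomal proteins stays open here too. Of 29 erythroid genes 0 passed the conservative test, 18 had an unadjusted p under 0.05, 13 were above when adjusted over the list alone, and 4 with recovered variances. Monocyte, macrophage and dendritic cell genes were at 0.82 (adjusted p = 0.0013): their list shifted down in all 3 comparisons with vehicle, in the combination by less than the sum. The S phase list was at -0.50 (adjusted p = 2.6e-09), the interferon list at -0.45 (adjusted p = 3.2e-08) and cholesterol synthesis at -0.58 (adjusted p = 3e-08). Of 56 S phase and 24 cholesterol genes 0 passed by the conservative test or by recovered variances, with 2 and 7 at an unadjusted p under 0.05. The stem cell list was at -0.22 and did not pass (adjusted p = 0.13).

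The 3 comparisons share their vehicle libraries, so overlap can arise without any shared effect. Palbociclib and ruxolitinib had 121 higher and 171 lower genes in common and none in opposite directions. Independent lists of these sizes would share 7.18 and 11.4. Palbociclib and the combination shared 615 higher and 419 lower genes against 117 and 70.1, with 1 in opposite directions. Ruxolitinib and the combination shared 122 and 168 against 21.9 and 39.1, with 5 in opposite directions. Simulated unchanged groups with shared vehicle libraries gave 0 shared calls in the same direction for each pair. They hold no changed genes, so they do not show how much shared controls add where genes do change. Across 12074 genes, which are not independent replicates, fold changes of palbociclib and the combination correlated at r = 0.813, with 0.523 in simulated unchanged groups, and a covariance of 0.726 against a simulated 0.0715. For palbociclib and ruxolitinib r was 0.244 against 0.495, with a covariance of 0.122 against 0.0695. Ruxolitinib and the combination gave r = 0.0213 against 0.505, with a covariance of 0.0161, below the simulated 0.0712. Signs matched in 73.1% of genes for palbociclib and ruxolitinib, against a simulated 66.6%. For palbociclib and the combination it was 77.4% against 66.6%, and for ruxolitinib and the combination 64.2% against 66.7%. Immunoglobulin and Y-linked genes were included, and no version without them was run. No split of 3 vehicle libraries leaves 2 in each part, so part of each excess may come from the shared controls.

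**Figure D3:**
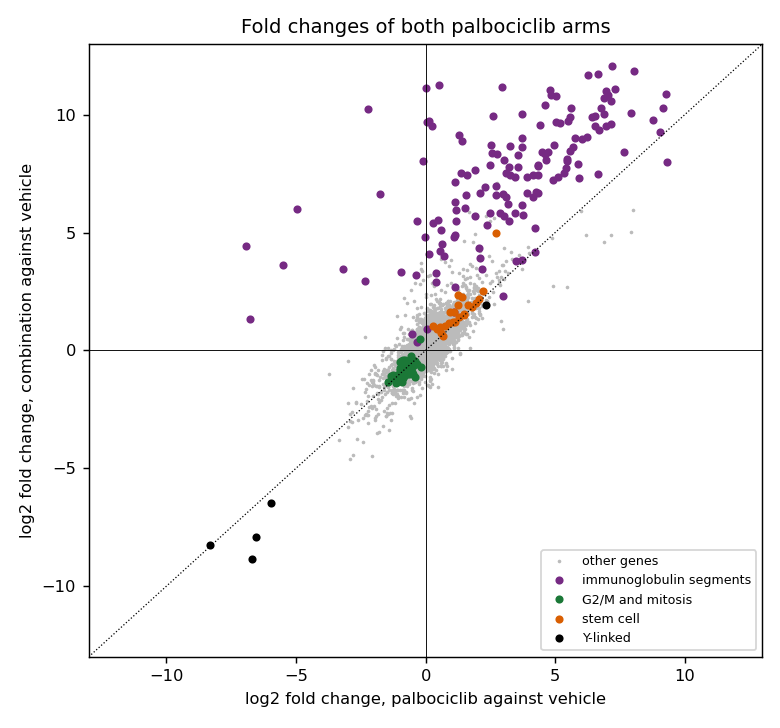
Log2 fold changes against vehicle with palbociclib (horizontal) and in the combination (vertical) for 12082 genes with a base mean of at least 50, with 3 more outside the axes. Immunoglobulin segments lie above the dotted line of equal change, stem cell genes lie above 0 and mitotic genes below 0 in both arms apart from the mitotic gene Pttg1 in the combination, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y lie at the lower left.

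The 33 list tests within each comparison used a preset inter-gene correlation of 0.01. Among the lists named above without a value at a correlation of 0.05, all that passed at 0.01 against vehicle passed at 0.05 as well. An estimated correlation could not be had without values per sample.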

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

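The test of monocyte genes against a lower share of sorted cells was chosen after its result was seen, and the separate naming of the ribosomal protein and non-coding patterns also came after their values were seen. The tests of plasma cell genes, X partners, length and GC, and receptor genes were written down before their results.

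A difference between drug arms drew attention to 12 genes off the sum of both drugs, of which Rtp4, Rai14 and Camsap2 lie outside the immunoglobulin genes together with Cgn and Gm49493. Rtp4 was higher with palbociclib and lower in the combination in the authors' deposited table, at 1.01 ± 0.25 and -0.79 ± 0.26. In cameraPR on the same differences 15 of 33 gene lists lay off the sum, 8 above and 7 below. A deviation of the vehicle libraries alone would also move lists off the sum. A further list of 11 plasma cell genes was also above the sum (adjusted p = 3.2e-09). Beside the lists given in the results the 15 included targets of TNF and NF-kB at a median of 0.70 (adjusted p = 2.6e-05), the unfolded protein and integrated stress response at 0.28 (adjusted p = 0.028) and lymphoid-primed progenitor genes at 0.50 (adjusted p = 0.037). Feedback targets of ERK were at -0.31 (adjusted p = 0.037), heat shock genes at -0.28 (adjusted p = 0.048) and the CDK-RB machinery at -0.18 (adjusted p = 0.048). At an inter-gene correlation of 0.05 the adjusted p of these was 0.0038 for TNF and NF-kB and 0.1 or above for the other 5.

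The authors' fit, and with it the base means and the modelled spread, held 12 libraries beside the 12 of these groups. Their values were not analysed here.

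Immunoglobulin segments were far higher in the combination, and 43 of 186 were higher with palbociclib. Of 11 plasma cell genes other than immunoglobulins, 10 were higher in the combination and 2 with palbociclib, so plasma cells or their RNA in the sorted libraries may be the source. The level of Jchain was 1264 normalised reads in vehicle, 11105 with palbociclib and 252586 in the combination, although lineage depletion and the LSK sort would remove such cells. A lower share of sorted cells would raise every other lineage. In the combination the B cell list (median 1.57) went up, but it holds Igkc, which belongs to the pattern itself. Of 29 erythroid genes 6 rose, the globin genes with Alas2 and Slc4a1, and 2 fell, Gata1 and Tspo2. Of 23 granulocyte genes 7 rose, among them Mmp9, Retnlg and Lyz2, and 7 fell, among them Elane, Mpo and Prtn3. Both lists mix genes of mature cells with genes of progenitors, so these counts do not test a lower share. The monocyte, macrophage and dendritic cell list had a median of -1.04 with 10 of 22 fold changes above 0. Of its genes 11 fell and 1 rose. These values met the bound written for rejecting a lower share, a median below 0 with more genes lower than higher. The rule as applied also required an upper quartile below 0, and that quartile was 0.53. The monocyte list also had a median of -0.94 with ruxolitinib, where 16 immunoglobulin segments were lower. Its fall can thus occur without the immunoglobulin rise, so the test does not decide and a lower share stays open. Whether 1 or all 3 combination libraries carry the signal cannot be read from these tables, and no biological explanation was tested.

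Of the Y-linked genes tested 4 were lower in both palbociclib arms and 1, Gm47283, was higher in all 3 comparisons; fewer libraries or cells of male origin in these groups may be the reason. Their 4 X-linked partners, which fewer male cells would raise, had a mean of medians of -0.37 ± 0.0859, which met the bound set beforehand for rejecting this explanation. That bound was badly chosen: neither fewer male cells nor a change of Y genes alone lowers the X partners, and with ruxolitinib, where Ddx3y, Kdm5d, Uty and Eif2s3y did not pass, the X partners had a median of -0.21. Other changes therefore move the X partners, the test does not decide, and a difference in origin cannot be told apart from a drug effect on Y genes. Xist, transcribed from the inactive X chromosome, was at a modelled 42253 normalised reads in vehicle, 66653 with palbociclib, 42338 with ruxolitinib and 71513 in the combination, with no comparison passing.

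Ribosomal protein genes and non-coding genes were higher in the combination, and both may carry technical differences between libraries. A fit of fold changes on transcript length and GC content explained 12.3% of their variance in the combination, 5.77% with palbociclib and 4.58% with ruxolitinib. It moved the ribosomal protein median from 0.63 (quartiles 0.48 to 0.80) to 0.24 (quartiles 0.03 to 0.52), between the bounds of 0.1 and 0.3 set beforehand, so a bias of length and GC stays open for part of the rise. The summed level of olfactory and vomeronasal receptor genes, which blood progenitors hardly transcribe, was 1.90 times that of vehicle in the combination, above the 1.5 set beforehand, with 1.24 for palbociclib and 1.23 for ruxolitinib. Genomic DNA or unspliced RNA in the combination libraries is therefore a candidate source of the non-coding rise, and no biological explanation was tested. Non-coding genes and pseudogenes without CT010467.1 summed to 1.34 times their level in vehicle. False calls at low counts may fill part of the 525 called higher, which was not tested.

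The test for other splits of the samples needs values per sample, which were not used here; 3 against 3 libraries make 10 splits, too few for a share under 0.05.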

How the results depend on the processing

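The recovered variances, and the counts of coding genes without immunoglobulin, T cell receptor and Y-linked genes, were chosen after the data were seen. No list called against vehicle changed direction. Which direction held more genes did change. In the combination it was 2471 higher and 1960 lower, but 1806 and 1891 among coding genes; at a base mean of at least 50 the numbers were nearly equal, at 1997 and 1994. Off the sum it was 8 above and 4 below, but 2 and 4 over every gene with a p-value and 2 and 3 at an adjusted p under 0.01. The difference from palbociclib held 1 higher and 2 lower, but 1 and 1 at an adjusted p under 0.01, 230 and 123 with a correlation of 0.5 and 188 and 84 with recovered variances. The coding counts, and the list counts with fold changes or ranks in place of the statistic, stayed within 1.5 times.

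At an adjusted p under 0.01 there were 596 genes for palbociclib, 179 for ruxolitinib, 2519 for the combination, 91 differing from ruxolitinib and 5 off the sum. Shared calls were then 109 for both single drugs, 465 for palbociclib and the combination, and 116 for ruxolitinib and the combination. At 0.1 there were 2004 for palbociclib, 447 differing from ruxolitinib, 6 differing from palbociclib and 33 off the sum. A fold change of at least 2 left 605, 250 and 1892 in the 3 comparisons with vehicle. These follow from the thresholds themselves.

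Adjusting over every gene with a p-value left 878 for palbociclib, 279 for ruxolitinib and 6 off the sum, since more genes were tested. A base mean of at least 50 left 1 gene differing between the combination and palbociclib, as Ighe and Cgn lie below it, and 9 shifted lists for palbociclib in place of 14; the cause of the latter was not tested. An inter-gene correlation of 0.05 left 7 of those 14, as it widens the null. A correlation of 0.5 between estimates gave 3064, 353 and 305 genes for the differences from ruxolitinib, from palbociclib and from the sum, and recovered variances 3020, 272 and 266. Both add the covariance that the conservative test leaves out. Recovered variances shared 201 of 212, 3 of 3 and 11 of 12 calls with it.

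Of 32 single list calls, 10 were lost at a correlation of 0.05, 8 at a base mean of at least 50, 11 with log2 fold changes and 4 with ranks. With fold changes the ribosomal protein list of the combination (adjusted p = 0.48), cholesterol synthesis with palbociclib (0.20) and MYC (0.073) and megakaryocyte genes (0.19) in the combination no longer passed, nor did ERK feedback targets with palbociclib (0.052). The B cell list of the combination did not pass with ranks (0.070), nor its heat shock list at a base mean of at least 50 (0.064). The cause was not tested. Over its alternatives the adjusted p of the ribosomal protein list ranged up to that 0.48.

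No paired analysis was possible because values per sample were not used here. For the same reason another tool, normalisation or low-count filter, fewer samples in the fit, a pseudocount, a replicate block, leaving out each library and an estimated inter-gene correlation were not run. The depth of 18.2 to 44.8 M reads limits genes with few reads: most false calls in simulated data had a base mean under 10.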

Other observations

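The imprinted gene test and the choice of genes here came after values were seen. A hypothesis was that imprinted genes, several of which mark quiescent stem cells, rise with the stem cell genes. The list shifted up in all 3 comparisons with vehicle, with 4 of 19 genes higher with palbociclib (adjusted p = 0.0029), 4 of 19 with ruxolitinib (adjusted p = 0.017) and 6 of 26 in the combination (adjusted p = 0.0072). The list holds Cdkn1c, which is also a stem cell gene here, and Zfp57 and Mkrn3, which had been noticed beforehand, so this is no independent evidence. All 3 comparisons also share the vehicle libraries, so a deviation of vehicle alone would move the list alike in each. Zfp57 was at 1.63, 1.29 and 1.55 with palbociclib, ruxolitinib and the combination in the authors' deposited table.

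Tcf15 was at 2.62, 2.36 and 2.47 and Erdr1 at 2.46, 2.51 and 2.27 in the same order in the authors' deposited table. The apoptosis gene Apaf1 was lower in all 3, at -0.74 ± 0.12, -0.54 ± 0.12 and -0.86 ± 0.12 in the authors' deposited table. As these folds share the vehicle libraries, their likeness across the 3 comparisons is no separate evidence. Ddit4 was at 1.43 ± 0.28 with palbociclib and 1.96 ± 0.28 in the combination in the authors' deposited table.

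Other genes were at nearly equal folds in both palbociclib arms and near 0 with ruxolitinib in the authors' deposited table. Eno1b was at 5.98, 0.43 and 5.92 with palbociclib, ruxolitinib and the combination, Gm4735 at 3.72, 0.14 and 3.47, and Wdfy1 at -1.23, -0.20 and -1.12, all in the authors' deposited table.

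Lists without a shift against vehicle are given here by adjusted p with palbociclib, ruxolitinib and the combination. They were p53 targets (0.88, 0.29 and 0.74), the unfolded protein and integrated stress response (0.63, 0.17 and 0.60), oxidative phosphorylation (0.63, 0.17 and 0.22) and the mitochondrial genome (0.071, 0.17 and 0.91). TGF-beta targets (0.86, 0.29 and 0.91) and T and NK cell genes (0.52, 0.97 and 0.46) did not pass either, nor did replication histones (0.11, 0.97 and 0.22) or genes of stroma and endothelium (0.35, 0.98 and 0.23). Within them Herpud1, Dnajb9 and Trib3 of the stress response rose in the combination together with the plasma cell gene Xbp1. The first 3 were at 1.11 ± 0.26, 1.12 ± 0.23 and 2.18 ± 0.59 in the authors' deposited table. The T cell factor gene Tcf7 fell there, at -2.77 ± 0.56, and Tgfb3 rose, at 2.97 ± 0.67, in the authors' deposited table.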
